A study of Mus musculus with 6 samples.

How the data were processed

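RNA from sorted hippocampal astrocytes was made into libraries with the Trio RNA-Seq system and sequenced from both ends, per the labels' protocols. FastQC 0.11.7, MultiQC 1.11, STAR 2.5.0a and DESeq2 1.30.1 are named with the mm10 build in the submitters' processing notes. The read counter and the gene annotation are not given in the sources used here.

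The values of the processed table of the whole series were inspected only to learn their unit and the depth of each column. The deposited values are not raw counts. Within each column they are whole multiples of the smallest non-zero value, as counts divided by a size factor per column would be, and that step differed between columns and was far larger in 1 column than in any other. The table has 6 columns of per-sample values, headed with a letter and a number, and 6 of them could not be matched to exactly 1 sample, because the sources used here do not tie either letter to a sorted population. These columns were left out of every comparison. The tests fixed before the data were examined were not run. They were to compare the populations gene by gene, over gene lists, and by the share of counts on markers of other cell types.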

Results

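The series profiled RNA from astrocytes of the mouse hippocampus after tamoxifen treatment and fear conditioning. The animals carried a green fluorescent reporter in astrocytes and a red reporter, tdTomato, that was switched on by a recombinase delivered with a virus and driven from Fos, an immediate early gene. Cells were sorted into 2 populations. GFP-positive, tdTomato-positive cells were termed learning-associated astrocytes, and GFP-positive, tdTomato-negative cells were termed non-learning-associated. Each population was represented by 3 samples by the labels, 6 in all.

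The comparison implied by this design is between the tdTomato-positive and the tdTomato-negative astrocytes. It was not made here. The labels used here did not state which columns of the processed table belonged to which population, or that the letters in the column names marked the populations. Columns were not assigned by their order or by their expression values, and whether any value bears on the assignment was not tested. Columns without a known sample were left out of comparisons, so no expression level, fold change or test is reported for either population. On inspection, the depth differed between the columns, and 1 of the 6 columns held far fewer reads than any other. The population it belongs to may therefore have in effect at most 2 usable replicates. Whether that column is usable was not tested.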

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

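A column was placed only where its name fitted exactly 1 sample, and 6 columns were left unplaced when the name had to equal a title, description or source name. The number was also 6 when the name was looked for inside any label or protocol text and when its letter was looked for as a word of its own in a label. These rules, and the next, were chosen after seeing the data. A name found in text shared by several samples would fit more than 1 sample and still leave its column unplaced. A letter that marked a whole population would do the same. The counts under these looser rules therefore do not show that the names or letters are absent from the labels. The number in each column's name fitted 1 sample of each population by the replicate numbers of the titles, so that rule cannot place a column and says nothing about the others. The normalizations, filters, tools and left-out samples chosen before the data were examined were not run, because columns without a known sample were not compared here. An unsigned comparison of the lettered sets was not run for that reason, although it needs no key to the letters. No paired analysis was possible between the populations because no label says which columns belong to each. The labels also do not say what the replicate numbers of the titles mark, so a key alone would not establish pairs. A fit of the lettered sets with the column number as a block needs no key either, and was left out by choice, like the unsigned comparison.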
